A study of Mus musculus with 41 samples.

How the data were processed

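Per the labels' protocols, spinal cords of Glast-dsRed mice were dissociated, incubated with a CD15 antibody and sorted by flow cytometry. RNA was isolated with a PicoPure kit, amplified with a NuGEN Ovation Pico kit from biological triplicates and labelled with Cy3 for one-colour Agilent arrays. Per the file headers, spots were quantified with Agilent Feature Extraction 10.7.3.1, and probe coordinates are those of the mouse assembly NCBI37. The deposited scanner files hold spot intensity on a linear scale, with the software's background-subtracted processed signal. The authors' value table holds 1 intensity per probe and array, also on a linear scale with values below 0. Its column medians lay between 28.4 and 31.3. The labels do not name the normalisation behind this table. Its columns have nearly the same distribution, as quantile normalisation leaves it, and its scale was read from a comparison of each column with the scanner values.

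Groups came from the population and stage in the sample labels. An array titled -/+ (P7) was put with the single positive cells, as the series text equates this code with +/-. It was unlike the other P7 arrays there, with log2 Aqp4 at 13.86 against 8.12 and 7.66 and Mrc1 at 10.90 against 4.91 and 5.21. Value table columns were mapped to samples by name, and each column's ranks over 55249 probes with 1 spot compared with every scanner file's. The best file reached a rank correlation of 1.000000 for each of the 41 columns and any other file at most 0.9513. The best file was the attached one for 1 column, and for the other 40 the attached file gave 0.7457 to 0.9234.

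The groups, comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The planned test used log2 processed scanner signal less each array's 75th percentile, with each file in the group of the sample it is attached to. Because of the conflict above, the values used are log2 of the authors' value table with values under 16 raised to 16. This change was made after the agreement of replicates and the levels of the gate genes had been seen and before any comparison was fitted, and the floor was also chosen after the files had been seen. Flags for spots well above background, slide and scan day were taken from the matching scanner file. The scanner signals with the matched files and with the files as attached were run as alternatives.

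Control spots were left out, and outlier spots (5470 of 2431505) where another spot of the probe remained. Of 55681 probes, 27235 were named by accession, 3581 by symbol and 565 by synonym through a RefSeq gene table of the assembly GRCm38.p6, used for names only, and 24300 have no gene name here. A probe was tested when it was well above background on at least 3 arrays (24421 probes), and the probe with the highest mean stood for its gene (17338 genes). In 5515 genes with several tested probes, other probes were at times called in the opposite direction, which is stated for named genes.

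Tests used limma 3.58.1 in R 4.3.3 with 1 mean for each of 19 groups over all 41 arrays, moderated variances with a trend (22 residual and 4.34 prior degrees of freedom) and Benjamini-Hochberg adjustment over genes. Groups with 1 array are assumed to vary like the others. All p-values of genes are from limma. A gene not well above background on any array of a group has a bound, the mean of the higher group against the higher of the lowest value well above background and the probe's own value on each array of the lower group. Differences were ranked as fitted, genes with a bound included, and those have no order among themselves.

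The 26 gene lists hold the gate genes, regulators and stages of glial and neuronal development, markers of other cell types the gates could hold, and pathways. Camera compared each list with all other genes, with a preset correlation of 0.01 and with an estimated one, adjusted over the 26 lists of a comparison. The genes named in each comparison are the gate genes Slc1a3, Fut4 and Fut9 where populations are compared, the regulators Sox9, Nfia, Nfib and Arhgef4, the 6 largest increases and 6 largest decreases among called genes with a symbol that is not a clone or accession and well above background on every array of the higher group, and up to 4 members of each called list with the smallest adjusted p. Some of them are not reported here.

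The arrays lay on 8 slides scanned on 3 days. Slide and scan day were fitted as fixed blocks where the comparison could be estimated, slide also as a random block (consensus correlation 0.0841), and comparisons were repeated within scan day 1 (27 arrays) and scan day 2 (9 arrays, 2 residual degrees of freedom). Other alternatives were normexp background correction with an offset of 50, quantile normalisation, the filter on dim probes, the mean of a gene's probes, the replicate number as a block, only the arrays compared, P7 as a further stage, E14.5 alone, no floor, the 3 arrays with a 75th percentile under 50 left out, and each array left out in turn.

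The fit was tested on simulated values of 17338 genes with the real group sizes. At a log2 change of 1, of 100 changed genes, 86 were recovered for double positive against double negative cells, 42 for the same at E10.5, 49 for double positive P4 against E14.5, 88 for the middle stages and 15 for the interaction with single positive cells. At a change of 2 these counts were 99, 93, 94, 99 and 69, with 11, 7, 9, 14 and 5 false calls. With no change limma called 0 genes and camera 0 lists, on simulated genes that are independent. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9.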

Results

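The series holds 41 one-colour expression arrays of cells sorted from the spinal cord of C57BL/6 mice that carry a Glast-dsRed reporter. Glast, the product of Slc1a3, is a glutamate transporter that the submitters describe as switched on when the cord turns to making glia. Dissociated cells were sorted on the reporter and on the surface sugar CD15 into double negative cells (dsRed-/CD15-), single positive cells (dsRed+/CD15-) and double positive cells (dsRed+/CD15+). The stated purpose was to take apart the middle stages of astrocyte development. Double negative cells gave 2 arrays at each of E10.5, E12.5, E14.5, E16.5, E18.5 and P4 and 1 at P7. Double positive cells gave 3 arrays at E10.5, E14.5 and P4, 2 at E16.5 and E18.5, and 1 at E12.5 and P7. Single positive cells gave 2 arrays at E14.5 and P4 and 3 at E16.5, E18.5 and P7. The labels speak of biological triplicates without saying which animals or litters gave which array. The p-values measure the spread between arrays within groups, pooled over all 19 groups, and not only that of the groups compared.

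The deposited sources disagree on which array belongs to which sample. Each of the 41 columns of the value table matched exactly 1 scanner file by ranks. For 40 it was attached to another sample, although all 41 sample descriptions name the attached file. The value table kept replicates of a group together, with 89.8% of the variance between groups, against 48.8% for the scanner files as attached. The highest of 100 shuffles of the labels, run on the value table only, gave 55.1%. Mean log2 Slc1a3 over E14.5 to P4 was 14.42 in double positive, 12.04 in single positive and 10.65 in double negative cells in the value table. With the files as attached it was 2.73, 3.71 and 3.81 on a scale relative to each array's 75th percentile. The values below are those of the value table, a choice made after these figures were seen, and counts with the files as attached stand beside them.

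The 75th percentile of the processed scanner signal ran from 21.8 to 394 (intensity), and 17241 to 42771 probes per array were well above background. The dimmest arrays were double negative ones, at 45.0 and 79.1 at E16.5, 105 and 136 at E18.5, 21.8 and 123 at P4 and 63.6 at P7, together with the double positive array of P7, also under 50. Arrays of 1 group correlated at a median r of 0.988 across genes (28 pairs, 0.888 to 0.996), and arrays of different groups at 0.888.

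**Figure D1:**
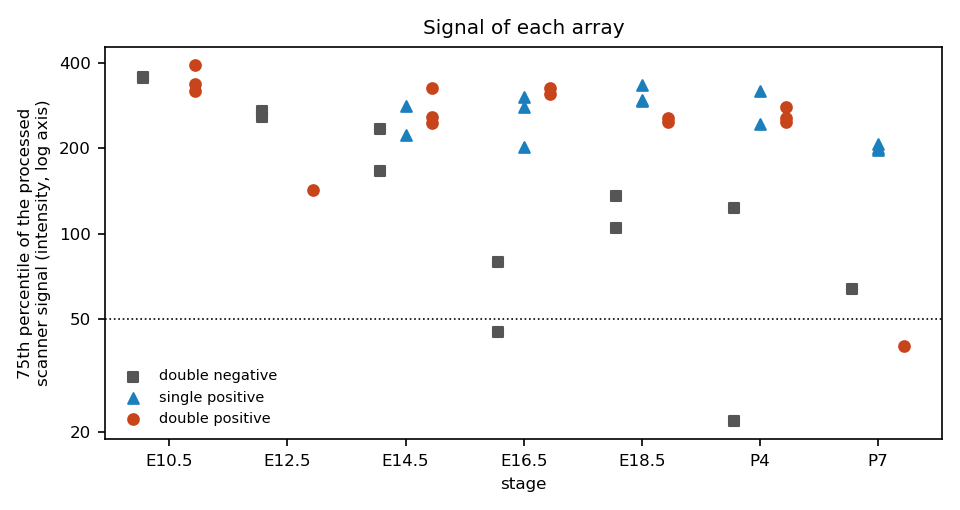
Signal of each of the 41 arrays by stage and population, as the 75th percentile of the processed scanner signal (intensity, log axis), each point 1 array placed by the rank match; the dotted line marks 50. The double negative arrays from E16.5 on and the double positive array of P7 lie lowest, down to 21.8.

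In what follows a value in brackets is a log2 difference ± its standard error, on values floored at 16, and a gene is called at an adjusted p under 0.05 in limma. A gene that was not well above background on any array of the lower group has only a bound, given as "at least N-fold". Members of a gene list are counted as higher or lower where they were called over all genes. Camera used a preset correlation of 0.01 unless stated.

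Double positive cells were first set against double negative cells, as the mean of the differences at E14.5, E16.5, E18.5 and P4 (10 against 8 arrays). The largest increases were in the mannose receptor gene Mrc1 (7.47 ± 0.58), the platelet factor gene Pf4 (7.34 ± 0.78), the coagulation factor gene F13a1 (7.12 ± 0.73), and Lyve1 (6.44 ± 0.55), Folr2 (at least 72.5-fold, adjusted p = 1.00e-15) and Ms4a7 (at least 64.1-fold, adjusted p = 5.80e-11). All 6 were higher on all 10 double positive arrays than on any double negative array, with an adjusted p of at most 5.27e-09. Mrc1 was well above background on 2 of 8 double negative arrays, Pf4 and F13a1 on 7 and Lyve1 on 1. The gate gene Slc1a3 (3.80 ± 0.23) and the CD15-synthesising enzyme gene Fut9 (3.00 ± 0.23) were higher too. The other fucosyltransferase gene, Fut4 (0.25 ± 0.23, adjusted p = 0.337), was not called and under normexp was lower, Fut4 (-0.68, adjusted p = 9.69e-06). Of the transcription factors and regulators named beforehand, Sox9 (4.30 ± 0.21), Nfia (1.50 ± 0.14) and Nfib (0.98 ± 0.20) and the guanine exchange factor gene Arhgef4 (3.05 ± 0.19) were higher, on 5 to 10 of the 10 arrays and with an adjusted p of at most 8.70e-05. The largest decreases were in Zdhhc22 (-8.67 ± 0.29), Hba-ps4 (-8.57 ± 0.34), the erythroid haem synthesis gene Alas2 (-8.38 ± 0.37), Unc93a2 (-8.34 ± 0.31), Slc6a20a (-7.76 ± 0.29) and the red cell anion exchanger gene Slc4a1 (-7.72 ± 0.33). Each lay below every double negative array on all 10, with an adjusted p of at most 1.55e-16. Hba-ps4 was well above background on 4 of 10 double positive arrays and Unc93a2 on 9. In the mouse assembly NCBI37 the probe of Slc1a3 lies on chromosome 15, 8584236 to 8584295 and that of Mrc1 on chromosome 2, 14253273 to 14253332.

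Among the gene lists fixed beforehand, 48 of 50 astrocyte maturation genes were higher in double positive cells and 1 was lower, with the potassium channel gene Kcnj10 (4.98 ± 0.14), S100b (2.36 ± 0.07) and Ttyh1 (4.29 ± 0.16) foremost (49 changed when adjusted over the list alone, camera adjusted p = 3.58e-14, or 0.198 with an estimated correlation). Beside them 29 of 31 microglia and macrophage genes were higher and 0 lower, with Cd68 (3.51 ± 0.27) first by adjusted p (29 changed when adjusted over the list alone, camera adjusted p = 6.68e-09, or 0.252 with an estimated correlation). Genes of radial glia and ventricular zone progenitors, such as Sox2 (4.04 ± 0.13) and Hes5 (5.78 ± 0.23), were higher in 20 of 30 cases. Gliogenic regulators, led by Dbx2 (5.76 ± 0.23) and Hey1 (2.37 ± 0.11), were higher in 18 of 24. Oligodendrocyte precursor genes were higher in 13 of 21, with Rlbp1 (4.68 ± 0.16) and Olig1 (5.30 ± 0.21) first. For these 3 lists, in order, 24, 20 and 16 changed when adjusted over the list alone, and camera's adjusted p was 1.10e-05, 5.61e-05 and 0.0208. With an estimated correlation the adjusted p was 0.198, 0.163 and 0.198. Dividing cells' genes differed as well, 44 of 52 higher and 3 lower, the lower ones being E2f2 (-3.93 ± 0.16), Ube2c (-2.48 ± 0.17) and Nusap1 (-1.98 ± 0.15) (47 changed when adjusted over the list alone, camera adjusted p = 1.10e-05, or 0.37 with an estimated correlation).

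Lower in double positive cells were all 21 measured erythroid genes, 35 of 41 general neuronal genes such as Syt1 (-4.58 ± 0.14) and Celf4 (-3.17 ± 0.11) and 31 of 36 genes of spinal neuron subtypes such as the opioid peptide gene Pdyn (-3.73 ± 0.16). So were 30 of 32 endothelial genes such as the tight junction gene Cldn5 (-3.30 ± 0.16) and 25 of 26 genes of fibroblasts and meninges such as Slc6a13 (-5.72 ± 0.34). In that order, 21, 37, 31, 30 and 25 changed when adjusted over the list alone, and camera's adjusted p was 1.95e-15, 4.61e-19, 9.33e-11, 6.27e-18 and 2.23e-13. An estimated correlation gave an adjusted p of 0.0891, 0.0891, 0.0219, 0.0377 and 0.198.

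In all 11494 of 17338 genes were called, 7026 higher and 4468 lower, 4574 of them by 2-fold or more. At E14.5 alone Fut9 (0.30), Nfib (0.86) and Ube2c (-0.12) (adjusted p 0.0753 to 0.823) lost their calls and Nusap1 (0.37, adjusted p = 0.341) changed sign. Within scan day 1 Nfib (0.74, adjusted p = 0.0881) lost its call, and within scan day 2 (2 residual degrees of freedom) the larger values of Fut9 (3.64), Nfia (1.74) and Nfib (1.48) (adjusted p 0.0546 to 0.0942) did not pass. With normexp background correction the share of higher calls fell from 61.1% to 48.4% and the median difference of all genes shifted by -0.16. The count was 11339 with slide and 11069 with scan day as a block. It was 8938 within scan day 1 (E18.5 and P4), 4010 within scan day 2 (E16.5 only), 6402 at E14.5 alone, and 0 with the files as attached (603 at an unadjusted p under 0.05). The astrocyte, macrophage and erythroid lists had median log2 differences of 3.20, 4.39 and -5.45 as reported. These were 3.32, 4.44 and -5.48 with slide as a block, 3.20, 4.34 and -5.40 with scan day as a block, 3.21, 3.56 and -4.82 within scan day 1, and 3.36, 4.72 and -6.76 within scan day 2.

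**Figure D2:**
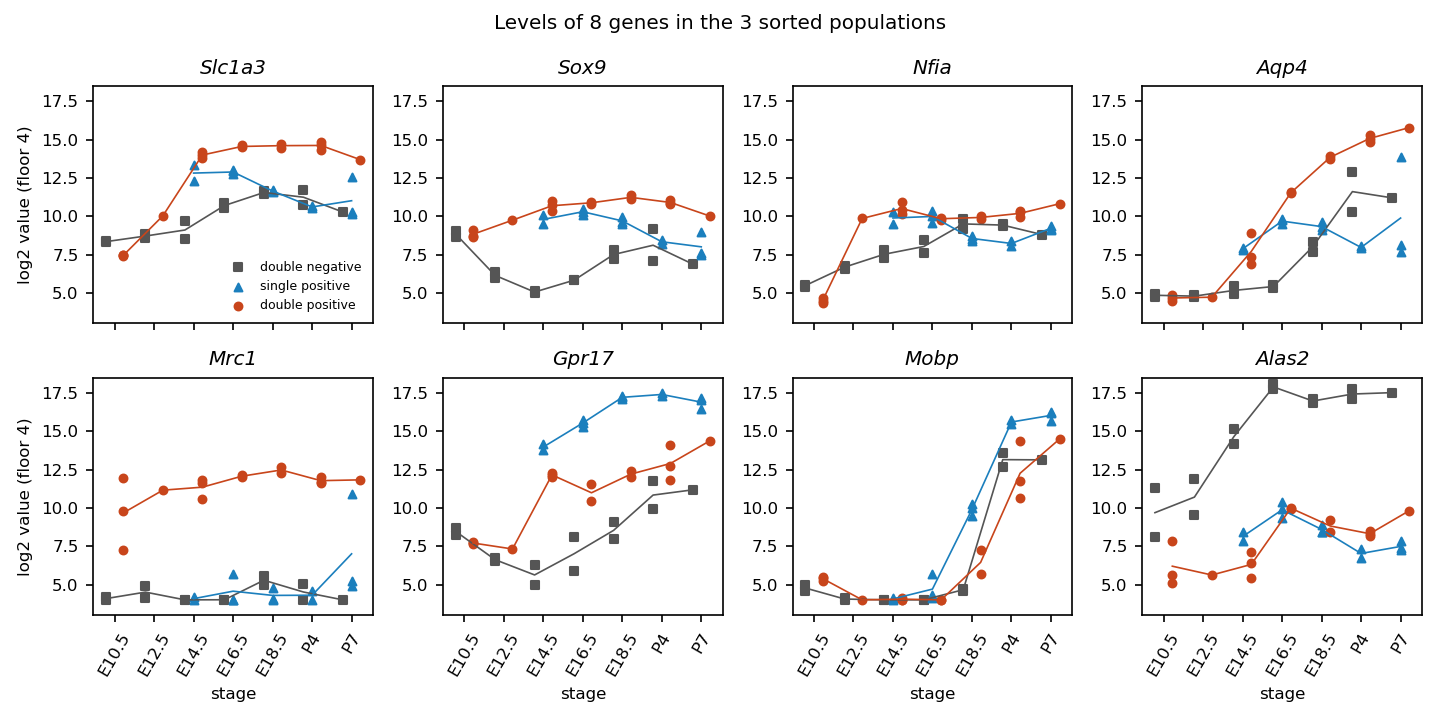
Log2 values of 8 genes on each of the 41 arrays by stage, in double negative (squares), single positive (triangles) and double positive cells (circles), with lines through the group means; values are floored at 4. Slc1a3 and Mrc1 are highest in double positive cells from E14.5 to P4, Gpr17 in single positive and Alas2 in double negative cells.

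The same mean over E14.5 to P4 set single positive against double negative cells (10 against 8 arrays). Here the largest increases were in the receptor gene Gpr17 (8.03 ± 0.29), the transcription factor gene Olig1 (6.82 ± 0.21), Scrg1 (6.10 ± 0.21), Omg (6.10 ± 0.20), the proteoglycan gene Bcan (5.51 ± 0.26) and the lipase gene Pnlip (at least 38.8-fold, adjusted p = 1.72e-18). They were higher on 8 to 10 of the 10 single positive arrays than on any double negative array, with an adjusted p of at most 5.27e-16. Olig1 was well above background on 6 of 8 double negative arrays, Scrg1 on 5 and Omg on 2. The gate genes gave Slc1a3 (1.34 ± 0.23), Fut9 (1.89 ± 0.23) and Fut4 (0.49 ± 0.23, adjusted p = 0.0563), which under normexp was Fut4 (-0.64, adjusted p = 2.02e-05). The regulators Sox9 (2.91 ± 0.21), Arhgef4 (1.66 ± 0.19), Nfib (0.57 ± 0.20) and Nfia (0.55 ± 0.14) exceeded every double negative array on 3 to 8 of the 10. Fut9 was well above background on 4 of 8 double negative arrays, and Fut4 on 2 and on 8 of 10 single positive arrays. The largest decreases were again in Unc93a2 (-8.57 ± 0.31), Hba-ps4 (-8.48 ± 0.34), Alas2 (-8.33 ± 0.37), Slc4a1 (-8.22 ± 0.33), Slc6a20a (-7.73 ± 0.29) and Zdhhc22 (-7.65 ± 0.29), below every double negative array on all 10 (adjusted p at most 2.19e-16). Unc93a2 and Slc6a20a were well above background on 9 of 10 single positive arrays and Hba-ps4 on 6. Within scan day 1, that is at E18.5 and P4, Slc1a3 (-0.27), Nfia (-1.07) and Nfib (-0.01) (adjusted p 6.61e-05 to 0.987) changed sign. Different probes of Zdhhc22 were called in opposite directions here.

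Oligodendrocyte precursor genes were higher in 19 of 21 cases, with Rlbp1 (4.48 ± 0.16) and Lhfpl3 (4.55 ± 0.18) after Olig1 and Gpr17 (19 changed when adjusted over the list alone, camera adjusted p = 2.02e-11, or 0.00126 with an estimated correlation). Myelin genes were higher in 19 of 26, among them Bcas1 (4.53 ± 0.18) and Cnp (3.49 ± 0.18), and astrocyte maturation genes in 30 of 50, led by S100b (3.82 ± 0.07). Cell cycle genes were higher in 44 of 52. For these lists, in order, 22, 32 and 48 changed when adjusted over the list alone, and camera's adjusted p was 9.38e-05, 0.0136 and 1.05e-07. Under an estimated correlation the adjusted p was 0.402, 0.712 and 0.402. Endothelial genes were lower in 31 of 32, with Cldn5 (-4.76 ± 0.16) and Egfl7 (-3.34 ± 0.13) first, and genes of pericytes and smooth muscle in 16 of 20, led by the receptor gene Pdgfrb (-3.02 ± 0.16). Microglia and macrophage genes were lower in 11 of 31 with 0 higher, led by Tmem119 (-2.40 ± 0.34). In the same order, 32, 16 and 11 changed when adjusted over the list alone, and camera's adjusted p was 4.18e-23, 6.20e-12 and 1.67e-04. The adjusted p became 0.0116, 0.0747 and 0.59 with an estimated correlation. Interferon response genes were lower in 20 of 29, with Rsad2 (-6.48 ± 0.20) and Isg15 (-4.44 ± 0.24) at the head (23 changed when adjusted over the list alone, camera adjusted p = 3.80e-06, or 0.306 with an estimated correlation). Rlbp1 was well above background on 5 of 8 double negative arrays, S100b on 7, and Rsad2 on 8 of 10 single positive arrays.

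Of 11658 genes called, 7640 were higher and 4018 lower, 4017 by 2-fold or more. At E14.5 alone Isg15 (-0.40) and Nfib (1.03) (adjusted p 0.0677 to 0.659) lost their calls, while Fut9 (-1.05), Pdgfrb (0.14) and Tmem119 (0.22) (adjusted p 0.119 to 0.899) changed sign. Within scan day 2, also E14.5, Arhgef4 (1.99), Bcan (7.09), Egfl7 (-0.98), Gpr17 (8.52), Isg15 (-0.62), Nfia (1.99), Nfib (1.07), Omg (5.58), Rsad2 (-2.84), Scrg1 (6.86), Slc1a3 (3.22) and Slc6a20a (-4.80) (adjusted p 0.0512 to 0.593) did not pass. There Fut9 (-1.38), Pdgfrb (0.12) and Tmem119 (1.41) (adjusted p 0.147 to 0.926) changed sign. An additive model with slide ended the call of Nfia (0.33, adjusted p = 0.446). P7 as a further stage ended that of Nfib (0.39, adjusted p = 0.0623), as did leaving out double negative P4 replicate 1, Nfib (0.44, adjusted p = 0.0542), or the 3 dimmest arrays, Nfib (0.34, adjusted p = 0.155). Under normexp the share of higher calls fell from 65.5% to 49.5% and the median difference shifted by -0.20. The count was 10642 with slide and 10577 with scan day as a block. It was 11433 within scan day 1 (E18.5 and P4), 494 within scan day 2 (E14.5 only), 4308 at E14.5 alone and 0 with the files as attached (123 unadjusted). The oligodendrocyte precursor, endothelial and macrophage lists had median log2 differences of 3.13, -2.88 and -1.04 as reported. These were 3.25, -2.83 and -0.66 with slide as a block, 3.25, -2.82 and -0.85 with scan day as a block, 3.88, -4.19 and -1.84 within scan day 1, and 2.90, -0.45 and -0.03 within scan day 2.

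Double positive and single positive cells share the dsRed gate and differ by CD15 (10 arrays each over E14.5 to P4). The largest increases in double positive cells were in Pf4 (8.86 ± 0.74), F13a1 (8.43 ± 0.69) and Mrc1 (7.61 ± 0.55), the scavenger receptor gene Stab1 (6.96 ± 0.45) and the complement genes C1qa (6.79 ± 0.58) and C1qc (6.74 ± 0.49). Each exceeded every single positive array on all 10, with an adjusted p of at most 1.56e-10. Pf4 was well above background on 8 of 10 single positive arrays, F13a1 on 7 and Mrc1 on 2. Within this gate Slc1a3 (2.46 ± 0.22) and Fut9 (1.11 ± 0.22) were higher as well, and Fut4 (-0.24 ± 0.21, adjusted p = 0.388) did not pass. Higher regulators were Arhgef4 (1.39 ± 0.18), Sox9 (1.39 ± 0.20) and Nfia (0.95 ± 0.14), while Nfib (0.41 ± 0.19, adjusted p = 0.0718) did not pass. The largest decreases were in the channel gene Pkd2l1 (-4.54 ± 0.32), Pnlip (-4.44 ± 0.18), the growth factor receptor gene Pdgfra (-4.43 ± 0.31), the nociceptin receptor gene Oprl1 (-4.27 ± 0.20), Tmem130 (-4.24 ± 0.16) and the somatostatin receptor gene Sstr1 (-4.15 ± 0.15). They lay below every single positive array on 9 to 10 of the 10 (adjusted p at most 3.97e-12). Pkd2l1 and Fut4 were well above background on 7 of 10 double positive arrays, and Fut4 on 8 of 10 single positive arrays.

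Astrocyte maturation genes were higher in 45 of 50 cases, with the glutamine synthetase gene Glul (2.04 ± 0.13) first, and 3 were lower, among them S100b (-1.46 ± 0.07) (48 changed when adjusted over the list alone, camera adjusted p = 2.43e-17, or 0.209 with an estimated correlation). Microglia and macrophage genes were higher in 29 of 31, with Fcer1g (6.71 ± 0.43) and C1qb (6.14 ± 0.40) first, and interferon response genes in 24 of 29, with Bst2 (3.59 ± 0.29) first. Early response genes, which also mark cell dissociation, were higher in 18 of 25, with Nfkbia (2.39 ± 0.19) and Atf3 (3.45 ± 0.27). For these 3 lists, in order, 29, 26 and 19 changed when adjusted over the list alone, and camera's adjusted p was 3.99e-22, 2.56e-09 and 4.00e-06. Estimating the correlation gave an adjusted p of 0.138, 0.172 and 0.318. Oligodendrocyte precursor genes were lower in 20 of 21, led by Lhfpl3 (-3.53 ± 0.17) and Cspg4 (-2.84 ± 0.14), and myelin genes in 20 of 26, led by Bcas1 (-3.09 ± 0.17) and Mbp (-2.24 ± 0.15). General neuronal genes were lower in 38 of 41, led by Syt1 (-3.10 ± 0.14) and Mapt (-3.20 ± 0.15). In the same order, 20, 23 and 39 changed when adjusted over the list alone, and camera's adjusted p was 7.59e-13, 3.76e-06 and 3.51e-20. With an estimated correlation the adjusted p was 5.76e-04, 0.209 and 0.138.

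Of 8429 genes called, 3650 were higher and 4779 lower in double positive cells, 2931 by 2-fold or more. At E14.5 alone Slc1a3 (1.18), Fut9 (1.35), Sox9 (0.89), Nfia (0.62), Arhgef4 (0.64), Bcas1 (-0.67), Nfkbia (0.72) and Atf3 (1.43) (adjusted p 0.0537 to 0.371) lost their calls. The additive model with slide ended the calls of Fut9 (0.77) and Nfia (0.91) (adjusted p 0.0561 to 0.303). With slide as a block the count was 7718, with scan day 8283, and within scan day 1 (all 4 stages) 7043. It was 4469 in an additive model of population, stage and slide, 1565 at E14.5 alone and 0 with the files as attached (1535 unadjusted). The astrocyte, macrophage and oligodendrocyte precursor lists had median log2 differences of 2.42, 5.74 and -2.44 as reported. These were 2.68, 5.85 and -2.43 with slide as a block, 2.45, 5.71 and -2.46 with scan day as a block, and 2.35, 5.67 and -2.52 within scan day 1.

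**Figure D3:**
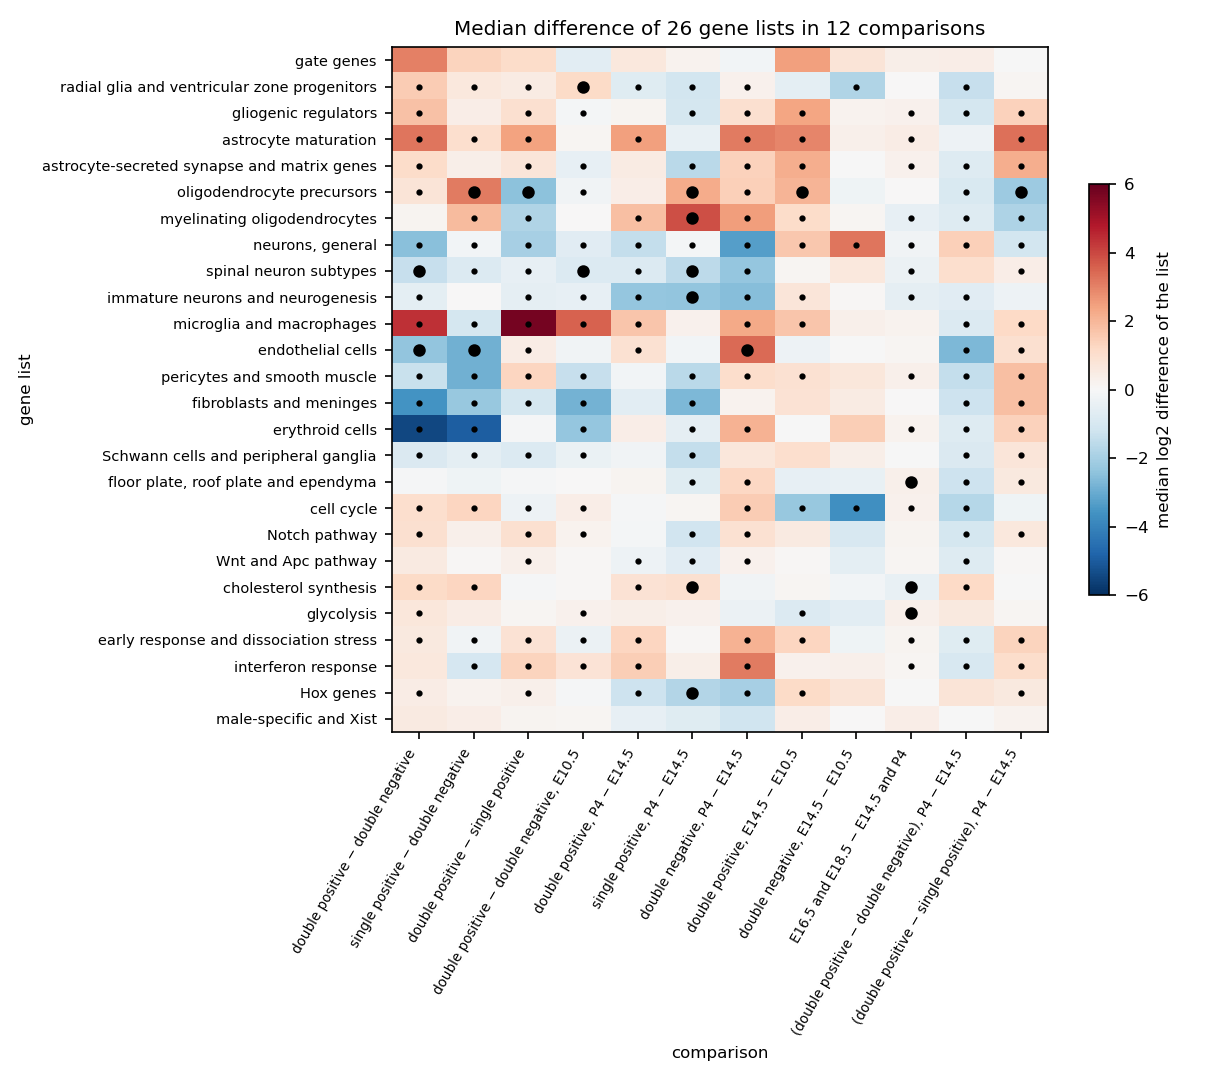
Median log2 difference of 26 gene lists in 12 comparisons (colour, from -6 to 6). Small dots mark lists that camera called with its preset correlation of 0.01, and large dots those also called with an estimated correlation. For double positive against double negative cells over E14.5 to P4 the macrophage and astrocyte lists have the highest medians, 4.39 and 3.20.

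E10.5, a stage before those of the submitters' design text, was compared on its own (3 double positive against 2 double negative arrays). The transcript of the reporter's own gene ran against the gates there, without passing the test. Slc1a3 (-0.89 ± 0.44, adjusted p = 0.303) was lower than both double negative arrays on all 3 double positive arrays. Fut4 (-0.61 ± 0.43, adjusted p = 0.605) did not pass either. The CD15 enzyme gene Fut9 (at least 2.99-fold, adjusted p = 0.0206) was higher. The largest increases were in the chemokine receptor gene Cx3cr1 (6.41 ± 0.99), and Tyrobp (5.93 ± 0.92), C1qc (at least 49.7-fold, adjusted p = 3.31e-04), Mrc1 (at least 48.4-fold, adjusted p = 0.0013), Ccl3 (at least 46.6-fold, adjusted p = 0.00107) and Aif1 (5.42 ± 0.82). Cx3cr1, Tyrobp and Aif1 were well above background on 1 of 2 double negative arrays. All 6 were above both double negative arrays on all 3, with an adjusted p of at most 0.0013. The double positive arrays were unlike, with macrophage list means of -1.68, 0.47 and 2.17. Without replicate 1 or 3 the values were Cx3cr1 (7.78 or 5.21), Tyrobp (7.32 or 4.77) and Aif1 (6.73 or 4.28), and the bounds 123-fold or 22.0-fold for C1qc, 111-fold or 22.1-fold for Mrc1 and 110.2-fold or 22.0-fold for Ccl3. Without double negative replicate 1 or 3 they were Cx3cr1 (7.05 or 5.76), Tyrobp (6.71 or 5.14) and Hbb-bh1 (-5.80 or -2.61), and without double positive replicate 2 or 3 Hbb-bh1 (-3.27 or -5.22). The largest decreases were in the collagen gene Col3a1 (-4.42 ± 0.69), the embryonic globin gene Hbb-bh1 (-4.21 ± 0.85), and Ddr2 (-4.19 ± 0.80), Twist1 (-4.14 ± 0.54), Meox2 (-4.10 ± 0.92) and Lum (-4.06 ± 1.04), all below both double negative arrays on all 3 (adjusted p at most 0.0122). Of the regulators Sox9 (-0.02 ± 0.40, adjusted p = 1.00), Arhgef4 (0.34 ± 0.37, adjusted p = 0.856) and Nfib (-0.88 ± 0.37, adjusted p = 0.199) did not pass, and Nfia (-0.97 ± 0.27) was lower. Nfia was well above background on 1 of 3 double positive arrays.

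At E10.5 genes of radial glia and ventricular zone progenitors were higher in 16 of 30 cases, with Sox2 (2.10 ± 0.25) and Gsx2 (1.69 ± 0.20) first (20 changed when adjusted over the list alone, camera adjusted p = 2.30e-16, or 0.0437 with an estimated correlation). Genes of spinal neuron subtypes were lower in 13 of 36, among them the vesicular acetylcholine transporter gene Slc18a3 (-3.15 ± 0.45) (18 changed when adjusted over the list alone, camera adjusted p = 1.54e-14, or 0.00418 with an estimated correlation). Microglia and macrophage genes were higher in 22 of 31, and genes of fibroblasts and meninges lower in 15 of 26 and erythroid genes in 11 of 21. For these, in order, 26, 19 and 17 changed when adjusted over the list alone, and camera's adjusted p was 2.61e-21, 9.68e-18 and 2.30e-16. An estimated correlation gave an adjusted p of 0.0996, 0.116 and 0.0861.

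At this stage 1334 genes were called, 529 higher and 805 lower. Normexp ended the calls of Fut9 (0.84) and Nfia (-0.40) (adjusted p 0.064 to 0.404), and so did the replicate number as a block, Fut9 (1.57) and Nfia (-0.89) (adjusted p 0.0648 to 0.114). Leaving out double negative replicate 1 ended the calls of Fut9 (1.85), Lum (-4.35) and Nfia (-1.04) (adjusted p 0.062 to 0.103). Without replicate 3 Fut9 (1.36), Hbb-bh1 (-2.61), Lum (-3.78) and Nfia (-0.90) (adjusted p 0.139 to 0.249) did not pass, and Fut9 (1.57), Lum (-3.79) and Nfia (-0.89) (adjusted p 0.0547 to 0.0941) lost theirs without double positive replicate 2. A fit of the 5 arrays alone left the differences as they were and ended the calls of Cx3cr1, Tyrobp, C1qc, Mrc1, Ccl3, Aif1, Hbb-bh1, Nfia, Sox2 and Gsx2 (adjusted p 0.0549 to 0.282), and the mean of its probes that of Nfia (-0.67, adjusted p = 0.137). The count was 1296 with slide and 1311 with scan day as a block. It was 393 in a fit of those 5 arrays alone, 766 without double negative replicate 1, 657 without double negative replicate 3, and 0 with the files as attached (460 unadjusted). The progenitor, spinal neuron and macrophage lists had median log2 differences of 1.15, -0.80 and 3.54, which a block cannot change, since all 5 arrays share slide and scan day.

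From E14.5 to P4 in double positive cells (3 arrays per stage) the largest gains were in the myelin gene Mobp (at least 295-fold, adjusted p = 9.66e-12), the intermediate filament gene Gfap (7.50 ± 0.79), the water channel gene Aqp4 (7.37 ± 0.88), the neurotensin receptor gene Ntsr2 (7.18 ± 0.76), and Htra1 (6.59 ± 0.70) and Agt (6.52 ± 0.71). Every P4 array was above every E14.5 array for these genes, and their adjusted p was at most 2.80e-07. Gfap was well above background on 2 of 3 E14.5 arrays. The bound of Mobp was 142-fold without P4 replicate 3, which had the highest myelin list mean of the 3 P4 arrays (2.10 against 0.87 and 0.18), and 516-fold without replicate 4. Without E14.5 replicate 1 the gain was Aqp4 (7.98). The largest losses were in the axon guidance receptor gene Robo3 (at least 467-fold, adjusted p = 5.33e-13), Ebf2 (at least 135-fold, adjusted p = 3.35e-09), the embryonic globin gene Hbb-y (at least 109.9-fold, adjusted p = 1.23e-07), and Ebf3 (-6.61 ± 0.34), Pou4f1 (-6.48 ± 0.36) and Lhx5 (at least 85.7-fold, adjusted p = 3.36e-12), each below every E14.5 array on all 3 (adjusted p at most 1.23e-07). Pou4f1 was well above background on 1 of 3 P4 arrays. The regulators Sox9 (0.21 ± 0.35, adjusted p = 0.712), Nfia (-0.31 ± 0.24, adjusted p = 0.362) and Arhgef4 (-0.04 ± 0.33, adjusted p = 0.965) did not pass, and Nfib (-1.53 ± 0.33) was lower on all 3 arrays (adjusted p = 8.19e-04).

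Astrocyte maturation genes rose in 42 of 50 cases with 0 lower, headed by S100b (4.84 ± 0.13) and Gpr37l1 (5.87 ± 0.48). Myelin genes rose in 20 of 26 and cholesterol synthesis genes in 21 of 24, headed by Msmo1 (1.84 ± 0.13). For these 3 lists, in order, 43, 22 and 22 changed when adjusted over the list alone, and camera's adjusted p was 1.14e-19, 6.04e-10 and 2.75e-11. Under an estimated correlation the adjusted p was 0.15, 0.138 and 0.0828. Genes of immature neurons fell in 21 of 26, with Ebf3 and Igfbpl1 (-6.18 ± 0.33) first, and general neuronal genes in 29 of 41, with Tubb3 (-5.85 ± 0.33) first. Hox genes fell in 28 of 39, with Hoxb7 (-1.67 ± 0.16) first. In that order, 23, 32 and 30 changed when adjusted over the list alone, and camera's adjusted p was 1.39e-20, 1.28e-12 and 4.08e-11. The adjusted p became 0.076, 0.15 and 0.134 with an estimated correlation. Microglia and macrophage genes rose in 11 of 31, with Tmem119 (2.83 ± 0.58) first (12 changed when adjusted over the list alone, camera adjusted p = 6.80e-05, or 0.512 with an estimated correlation).

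Of 5509 genes called, 2932 were higher and 2577 lower at P4. The count was 5951 with slide and 5460 with scan day as a block, 5353 within scan day 1 and 1057 with the files as attached. The astrocyte, immature neuron and macrophage lists had median log2 differences of 2.46, -2.33 and 1.67. A block cannot change these, since each of 3 slides, all of scan day 1, held 1 array of either stage.

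In single positive cells (2 arrays per stage) the largest gains were in Mobp (at least 2984-fold, adjusted p = 2.08e-12), Sgk2 (at least 135-fold, adjusted p = 9.50e-09), Tmem125 (at least 105-fold, adjusted p = 3.20e-08), Mag (6.60 ± 0.67) and Bfsp2 (6.37 ± 0.57) and the tight junction gene Cldn11 (6.16 ± 0.63). The largest losses were in Hbb-y (at least 2765-fold, adjusted p = 1.22e-09), Robo3 (-8.52 ± 0.61), Hba-x (at least 255-fold, adjusted p = 8.86e-08), Igfbpl1 (-7.19 ± 0.41), Ebf3 (-6.36 ± 0.42) and Mfap4 (-6.17 ± 0.77). Both P4 arrays lay beyond both E14.5 arrays for all 12 genes, with an adjusted p of at most 1.00e-06. Robo3 and Igfbpl1 were well above background on 1 of 2 P4 arrays. Without E14.5 replicate 1 or 3 the bounds were 5745-fold or 1331-fold for Hbb-y and 466-fold or 140.1-fold for Hba-x, and the loss was Mfap4 (-5.52 or -6.82). The regulators fell here, Nfib (-2.67 ± 0.41), Nfia (-1.66 ± 0.30), Sox9 (-1.46 ± 0.43) and Arhgef4 (-1.27 ± 0.40), on both arrays (adjusted p at most 0.022).

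Myelin genes rose in 22 of 26 cases, with Sirt2 (4.47 ± 0.29) after Mobp, and oligodendrocyte precursor genes in 15 of 21, with Neu4 (at least 18.6-fold, adjusted p = 3.47e-12) and Tnr (3.95 ± 0.43) first. Cholesterol synthesis genes rose in 19 of 24. Genes of immature neurons fell in 18 of 26, of spinal neuron subtypes in 19 of 36, with Lhx5 (at least 60.4-fold, adjusted p = 1.02e-09) first, and Hox genes in 29 of 39, with Hoxb5 (-3.41 ± 0.31) first. All 6 lists were called under either correlation: in order, 25, 16, 22, 18, 25 and 31 changed when adjusted over the list alone, and camera's adjusted p was 4.01e-19, 3.44e-11, 8.84e-13, 3.95e-17, 1.90e-12 and 1.09e-18. Estimating the correlation gave an adjusted p of 0.02, 0.00159, 0.0282, 0.0282, 0.00489 and 0.02. Astrocyte-secreted synapse and matrix genes fell in 10 of 20, with Megf10 (-2.96 ± 0.31) first (15 changed when adjusted over the list alone, camera adjusted p = 3.52e-05, or 0.0988 with an estimated correlation). Genes of fibroblasts and meninges fell in 14 of 26, from list means of 2.22 and 0.19 at E14.5 to -1.36 and -1.28 at P4, and genes of pericytes in 10 of 20. For this pair 19 and 12 changed when adjusted over the list alone, and camera's adjusted p was 1.54e-09 and 1.33e-08. With an estimated correlation the adjusted p was 0.217 and 0.0888. Astrocyte maturation genes were not called as a list, with 6 higher and 12 lower of 50 (camera adjusted p = 0.19).

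The interval changed 3787 genes in single positive cells, 1961 higher and 1826 lower at P4. The count was 3280 with slide and 3362 with scan day as a block, and 2583 within scan day 1. It was 1932 in a fit of the 4 arrays alone, 2461 without P4 replicate 1 and 2441 with the files as attached. The myelin, immature neuron and Hox lists had median log2 differences of 3.87, -2.37 and -1.78 as reported. These were 3.87, -2.48 and -1.85 with slide as a block, 3.96, -2.48 and -1.87 with scan day as a block, and 3.82, -2.60 and -1.99 within scan day 1. Slide as a block ended the call of Arhgef4 (-1.31, adjusted p = 0.0592) and scan day 1 those of Sox9 (-1.76) and Arhgef4 (-1.48) (adjusted p 0.065 to 0.075). The fit of the 4 arrays alone, with the same differences, ended those of Sox9, Nfia, Arhgef4 and Megf10 (adjusted p 0.0552 to 0.0768). Without E14.5 replicate 3 Sox9 (-1.15) and Arhgef4 (-1.06) (adjusted p 0.153 to 0.161) did not pass. Nor did Sox9 (-1.32, adjusted p = 0.113) without P4 replicate 1 and Arhgef4 (-1.07, adjusted p = 0.164) without P4 replicate 3.

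In double negative cells (2 arrays per stage, the P4 ones at a 75th percentile of 21.8 and 123) the largest gains at P4 were in Mobp (at least 481-fold, adjusted p = 2.90e-11), Gda (at least 259-fold, adjusted p = 2.19e-12), Ly6c1 (7.42 ± 0.53), S100b (7.14 ± 0.15), Rsad2 (7.01 ± 0.42) and Msln (at least 86.8-fold, adjusted p = 2.30e-10). The largest losses were in Scrt1 (-7.96 ± 0.66), Robo3 (-7.50 ± 0.61), Hoxb8 (-7.40 ± 0.48), Lhx5 (at least 129-fold, adjusted p = 1.02e-11), Hbb-y (-7.24 ± 0.95) and Crabp1 (-7.23 ± 0.43). Both P4 arrays lay beyond both E14.5 arrays for each (adjusted p at most 4.40e-07). S100b was well above background on 1 of 2 E14.5 arrays, and Scrt1, Robo3 and Crabp1 on 1 of 2 P4 arrays. The P4 arrays, replicates 1 and 2, were unlike (r = 0.888), with list means of -0.84 and 0.99 for macrophages and -0.39 and 3.36 for fibroblasts. Without replicate 1 or 2 the bounds were 124-fold or 539.8-fold for Gda and 157-fold or 48.2-fold for Msln, and the values Sox9 (2.00 or 4.11), Scrt1 (-6.09 or -9.83), Rsad2 (5.96 or 8.05), Kcnj10 (5.13 or 6.43) and Nsg1 (-3.08 or -4.70). The regulators Sox9 (3.06 ± 0.43) and Nfia (1.90 ± 0.30) rose, Nfib (-1.61 ± 0.41) fell, and Arhgef4 (0.75 ± 0.40, adjusted p = 0.112) did not pass.

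All 32 endothelial genes rose, with Mfsd2a (4.37 ± 0.27) first (32 changed when adjusted over the list alone, camera adjusted p = 2.37e-21, or 0.0333 with an estimated correlation). Astrocyte maturation genes rose in 41 of 50, with Kcnj10 (5.78 ± 0.29) after S100b, and microglia and macrophage genes in 20 of 31. General neuronal genes fell in 35 of 41, with Nsg1 (-3.89 ± 0.31) first. For these 3 lists, in order, 44, 20 and 38 changed when adjusted over the list alone, and camera's adjusted p was 8.26e-12, 1.26e-05 and 6.41e-10. An estimated correlation gave an adjusted p of 0.256, 0.399 and 0.209. Erythroid genes went both ways, 12 up and 3 down of 21: the embryonic globin gene Hbb-y was among those that fell and the haem synthesis gene Fech (2.70 ± 0.41) among those that rose (17 changed when adjusted over the list alone, camera adjusted p = 0.00981, or 0.503 with an estimated correlation).

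In double negative cells 10266 genes were called, 4092 higher and 6174 lower. Under normexp the share of higher calls rose from 39.9% to 51.2% and the median shifted by 0.25. The count was 8627 with slide and 8404 with scan day as a block. It was 8759 without the arrays under a 75th percentile of 50, 891 in a fit of the 4 arrays alone and 0 with the files as attached (1353 unadjusted). The endothelial, astrocyte and neuronal lists had median log2 differences of 3.41, 3.12 and -3.29 as reported. These were 3.58, 3.58 and -3.22 with slide as a block, and 3.66, 2.99 and -3.23 with scan day as a block. The fit of the 4 arrays alone, with the same differences, ended the calls of Sox9, Nfia, Nfib, Fech, Nsg1 and Scrt1 (adjusted p 0.0562 to 0.123), and leaving out P4 replicate 1, 1 of the arrays under 50, that of Nfib (-1.09, adjusted p = 0.0628), as without all 3, Nfib (-1.09, adjusted p = 0.0569).

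All 5 arrays of E10.5 were on 1 slide scanned on a day of its own, so stage and slide cannot be told apart from E10.5 to E14.5. In double positive cells (3 arrays per stage) the genes Nfix (7.87 ± 0.33), Nfib (6.06 ± 0.33) and Nfia (6.00 ± 0.24) rose together with Arhgef4 (4.73 ± 0.33) and Sox9 (1.86 ± 0.35) (adjusted p at most 7.80e-05). Among the other leading gains were Bcan (9.55 ± 0.44), Hopx (8.75 ± 0.53) and Aldoc (8.34 ± 0.49) and the folate enzyme gene Aldh1l1 (7.83 ± 0.69). Nfix and Nfia were well above background on 1 of 3 E10.5 arrays. The largest losses were in Hbb-bh1 (-7.06 ± 0.76) and Krt18 (-6.20 ± 0.73), the myeloid enzyme gene Mpo (-6.10 ± 1.22), Fndc3c1 (at least 60.4-fold, adjusted p = 1.09e-16), Oc90 (-5.89 ± 0.50) and Krt8 (at least 53.5-fold, adjusted p = 1.16e-10). Krt18, Mpo and Oc90 were well above background on 1 of 3 E14.5 arrays. Without E10.5 replicate 3 the bound of Krt8 was 34.8-fold and the values Hbb-bh1 (-6.05), Krt18 (-5.58), Mpo (-4.85) and Oc90 (-4.84). The value was Mpo (-7.88) without replicate 1, Hbb-bh1 (-8.00) without replicate 2 and Krt18 (-6.81) without E14.5 replicate 3. All 3 E14.5 arrays lay beyond all 3 E10.5 arrays for each of these genes (adjusted p at most 1.42e-04).

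Gliogenic regulators rose in 17 of 24 cases, with Mmd2 (at least 186-fold, adjusted p = 7.44e-15) next after Nfia and Nfix, and astrocyte maturation genes in 38 of 50. Astrocyte-secreted synapse and matrix genes rose in 14 of 20, and oligodendrocyte precursor genes in 15 of 21, with Rlbp1 (at least 100.4-fold, adjusted p = 1.96e-16) and Cspg4 (4.97 ± 0.25) first. For these, in order, 19, 40, 14 and 16 changed when adjusted over the list alone, and camera's adjusted p was 3.55e-08, 4.30e-13, 2.86e-07 and 3.46e-07. Under an estimated correlation the adjusted p was 0.0581, 0.38, 0.113 and 0.0212. All 52 cell cycle genes fell, with Rrm1 (-2.04 ± 0.15) and Cdt1 (-3.04 ± 0.23) first, and so did 14 of 20 glycolysis genes, with Gapdh (-1.05 ± 0.09) first. In that order, 52 and 20 changed when adjusted over the list alone, and camera's adjusted p was 1.43e-22 and 0.00531. The adjusted p became 0.113 and 0.38 with an estimated correlation. The comparison called 8858 genes, 4321 higher and 4537 lower, and 328 with the files as attached. No fit with slide or scan day as a block can give this contrast.

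In double negative cells (2 arrays per stage) the largest gains over the same interval were in Hbb-bs (8.87 ± 0.74), the neuropeptide gene Npy (7.42 ± 0.50), Hbb-bt (7.26 ± 0.79), the glutamate receptor gene Grm5 (at least 139-fold, adjusted p = 2.98e-11), and Neurod2 (6.78 ± 0.50) and Hbb-b2 (6.65 ± 1.20). The largest losses were in Pax1 (at least 86.2-fold, adjusted p = 5.05e-09), Fndc3c1 (at least 89.0-fold, adjusted p = 1.26e-15), Meox1 (-6.40 ± 0.68), Actc1 (-6.05 ± 0.90) and Dusp9 (at least 54.5-fold, adjusted p = 1.01e-12) and the topoisomerase gene Top2a (-5.77 ± 0.76). Both E14.5 arrays lay beyond both E10.5 arrays (adjusted p at most 4.64e-05). Meox1 and Top2a were well above background on 1 of 2 E14.5 arrays. The regulators Nfib (4.33 ± 0.41), Arhgef4 (2.23 ± 0.40) and Nfia (2.04 ± 0.30) rose, and Sox9 (-3.79 ± 0.43) fell. The globin genes Hbb-bs, Hbb-bt and Hbb-b2 are near-identical copies whose probes can share signal, so their values are uncertain as to the copy. Without E10.5 replicate 1 or 3 the gains were Hbb-bs (8.12 or 9.62), Hbb-bt (6.56 or 7.96), Hbb-b2 (5.69 or 7.61) and Neurod2 (7.58 or 5.98).

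General neuronal genes rose in 38 of 41 cases, with Celf4 (4.90 ± 0.24) first, and cell cycle genes fell in 51 of 52, with Kif20a (-4.37 ± 0.28) first. Genes of radial glia and ventricular zone progenitors fell in 24 of 30, with Sox2 (-3.33 ± 0.27) first. For these, in order, 38, 51 and 27 changed when adjusted over the list alone, and camera's adjusted p was 1.42e-19, 1.29e-30 and 8.18e-07. Estimating the correlation gave an adjusted p of 0.172, 0.171 and 0.428. From E10.5 to E14.5 8048 genes were called in double negative cells, 4152 higher and 3896 lower, and 0 with the files as attached (2348 unadjusted). Under normexp the median shifted by 0.20.

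The middle stages were set as the mean of E16.5 and E18.5 against the mean of E14.5 and P4 in double positive and single positive cells together (10 arrays each). A gene that rises or falls steadily gives a small value here, and one that rises only by P4 a negative one. The inositol phosphatase gene Inpp5j (2.92 ± 0.33), Pla2g3 (2.28 ± 0.31) and Odf3b (2.25 ± 0.23) and the globin genes Hbb-bs (2.44 ± 0.34), Hbb-b2 (2.38 ± 0.55) and Hbb-bt (1.91 ± 0.36) were higher in the middle stages. In turn Ppp1r14a (-2.16 ± 0.23), Chst8 (-1.73 ± 0.15), Pdlim2 (-1.71 ± 0.25), Clvs1 (-1.61 ± 0.25), Scn10a (-1.59 ± 0.43) and Islr2 (-1.47 ± 0.27) were lower, with an adjusted p of at most 0.0287. Scn10a was well above background on 3 of 10 E16.5 and E18.5 arrays. Arrays of the 2 sides overlapped for most of them: 2 to 10 of the 10 middle-stage arrays were above all others for the former and 0 to 9 of the 10 below all others for the latter. The regulators Sox9 (0.60 ± 0.20, adjusted p = 0.0894), Arhgef4 (0.57 ± 0.18, adjusted p = 0.0801), Nfib (-0.07 ± 0.19, adjusted p = 0.95) and Nfia (-0.13 ± 0.14, adjusted p = 0.783) did not pass.

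Cholesterol synthesis genes had a negative value in 17 of 24 cases, among them Fdps (-0.67 ± 0.08). The rise at P4 enters it: the list mean was -0.11 ± 0.07, 0.20 ± 0.07 and 0.96 ± 0.07 (SD) at E14.5, E18.5 and P4 in single positive cells. Glycolysis genes were higher in 8 of 20, with Ldha (0.69 ± 0.10) first. Genes of floor plate, roof plate and ependyma were higher in 11 of 28. The leading members of the last list, Tmem212 (1.59 ± 0.24), Dnah5 (0.73 ± 0.11), Dynlrb2 (1.38 ± 0.21) and Tekt1 (0.97 ± 0.18), include genes of motile cilia. These 3 lists were called under either correlation: in order, 23, 13 and 14 changed when adjusted over the list alone, and camera's adjusted p was 3.26e-29, 7.68e-12 and 7.04e-09. With an estimated correlation the adjusted p was 0.00225, 0.00861 and 0.00927. Myelin genes had a negative value in 6 of 26, with Mobp (-2.74 ± 0.30) first (12 changed when adjusted over the list alone, camera adjusted p = 4.57e-12, or 0.0686 with an estimated correlation). Mobp rose late, with 4.06 ± 0.09, 9.90 ± 0.40 and 15.61 ± 0.20 at these stages.

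The comparison called 801 genes, 461 higher and 340 lower. Slide as a block ended the call of Scn10a (-1.47, adjusted p = 0.0703), and so did no filter on dim probes, Scn10a (-1.59, adjusted p = 0.0506), and leaving out any of 10 arrays in turn (-1.46 to -1.63). Within scan day 1 Scn10a (-1.66) and Tekt1 (0.84) (adjusted p 0.095 to 0.236) did not pass. Processed scanner signals moved the share of higher calls from 57.6% to 47.2%. The count was 790 with slide and 712 with scan day as a block, and 377 within scan day 1. It was 1924 in a fit of the 20 arrays alone, 1493 without the arrays under a 75th percentile of 50, 533 without single positive P4 replicate 1 and 1241 with the files as attached. The cholesterol, glycolysis and ependyma lists had median log2 differences of -0.45, 0.30 and 0.31 as reported. These were -0.45, 0.28 and 0.29 with slide as a block, -0.47, 0.27 and 0.30 with scan day as a block, and -0.49, 0.26 and 0.32 within scan day 1.

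**Figure D4:**
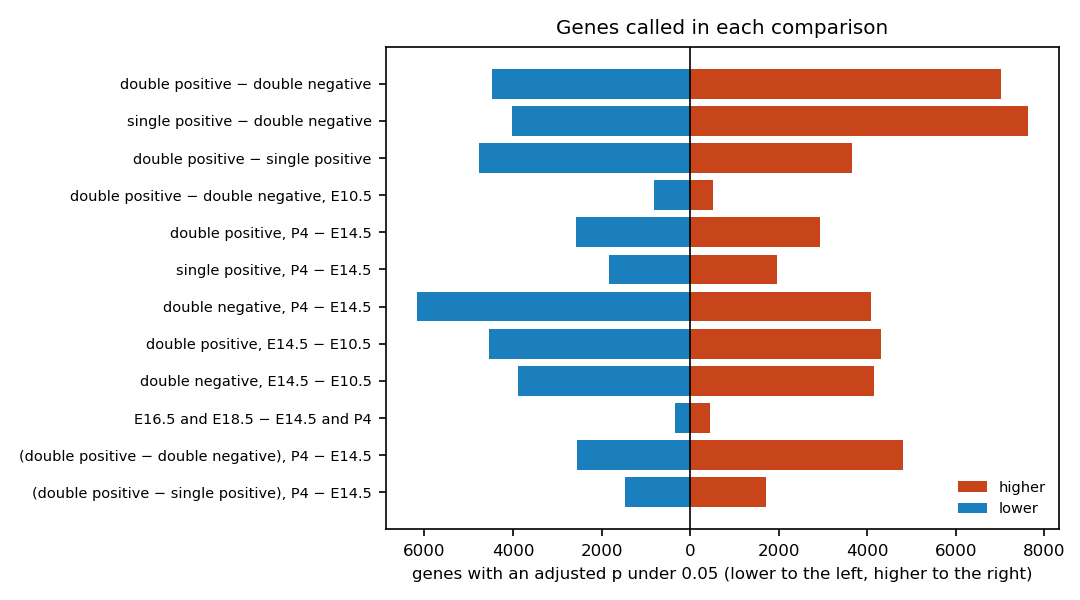
Genes called at an adjusted p under 0.05 in each of the 12 comparisons, higher to the right and lower to the left of 0. The counts run from 801 for the middle stages to 11658 for single positive against double negative cells.

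Whether the change from E14.5 to P4 differed between populations was tested as an interaction. Between double positive and double negative cells, some leading genes on one side rose in double positive and fell in double negative cells, in log2 from E14.5 to P4: Car10 (4.64 against -4.39), Npy (2.87 against -4.73), Dclk3 (4.24 against -3.25), Jakmip1 (4.27 against -2.28) and Grm5 (3.84 against -2.47). On the other side, with the more negative value in double positive cells, stood Plekha4 (-2.22 against 3.92), Rsad2 (1.16 against 7.01), Isg20 (0.65 against 6.22), Insm1 (-5.87 against -0.38) and Crb2 (-2.91 against 2.51). The differences between the changes were 9.03 ± 0.77 for Car10 and -6.15 ± 0.63 for Plekha4, and the adjusted p was at most 6.11e-07 for all 10. The changes of Sox9 (0.21 against 3.06) and Nfia (-0.31 against 1.90) differed by -2.84 ± 0.56 and -2.22 ± 0.39, while Nfib (0.08 ± 0.53, adjusted p = 0.919) and Arhgef4 (-0.78 ± 0.52, adjusted p = 0.23) did not pass. Without double negative P4 replicate 1 or 2 the differences were Crb2 (-4.24 or -6.62), Dclk3 (6.32 or 8.65), Insm1 (-6.34 or -4.62), Isg20 (-4.94 or -6.20), Plekha4 (-6.83 or -5.46), Rsad2 (-4.80 or -6.89) and Sox9 (-1.79 or -3.90), and without double positive E14.5 replicate 1 or 3 Grm5 (7.07 or 5.59). Endothelial genes had the more negative change in double positive cells in 30 of 32 cases, with Mfsd2a (-4.51 ± 0.35) first. General neuronal genes had the more positive change in 21 of 41. For these, in order, 30 and 25 changed when adjusted over the list alone, and camera's adjusted p was 9.63e-19 and 0.0142. An estimated correlation gave an adjusted p of 0.0586 and 0.572. Of 7355 genes called, 4804 were higher and 2551 lower in this sense, and normexp shifted the median by -0.15. The count was 5979 with slide and 5794 with scan day as a block, 3930 in a fit of the 10 arrays alone and 0 with the files as attached (67 unadjusted). The endothelial and neuronal lists had median log2 differences of -2.68 and 1.42 as reported. These were -2.83 and 1.50 with slide as a block, and -2.78 and 1.51 with scan day as a block.

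Between double positive and single positive cells the leading genes on one side rose in double positive cells, Htra1 (6.59 against -1.11), Svep1 (5.44 against -2.02), Aqp4 (7.37 against 0.09), Paqr6 (5.24 against -1.71), Npy (2.87 against -3.97) and Il33 (4.03 against -2.32). Opposite them stood Gsx1 (-3.40 against 2.77), Sema5b (-3.17 against 1.36), Dll3 (-3.75 against 0.49), Bcas1 (-0.29 against 3.70), Inava (-1.05 against 2.78) and Asic4 (-3.34 against 0.34). The differences between the changes were 7.70 ± 1.10 for Htra1 and -6.17 ± 0.46 for Gsx1, with an adjusted p of at most 5.55e-04 over the 12. Without single positive E14.5 replicate 1 or 3 the differences were Htra1 (6.22 or 9.18) and Svep1 (5.93 or 9.01), without double positive E14.5 replicate 1 Aqp4 (7.88) and without double positive P4 replicate 3 Bcas1 (-4.58). The regulators gave Sox9 (1.67 ± 0.56), Nfia (1.35 ± 0.39), Arhgef4 (1.24 ± 0.52, adjusted p = 0.102) and Nfib (1.15 ± 0.53, adjusted p = 0.143). Oligodendrocyte precursor genes had the more negative change in double positive cells in 14 of 21 cases, with Neu4 (-3.81 ± 0.33) first. Astrocyte maturation genes had the more positive change in 40 of 50, with S100b (1.57 ± 0.20) first, and gliogenic regulators in 13 of 24, with Hey2 (4.00 ± 0.68) and Id2 (2.85 ± 0.51) first. For these, in order, 16, 44 and 16 changed when adjusted over the list alone, and camera's adjusted p was 8.33e-10, 1.38e-22 and 9.46e-07. Under an estimated correlation the adjusted p was 0.00271, 0.21 and 0.084. Of 3192 genes called, 1715 were higher and 1477 lower. The count was 2764 with slide and 2750 with scan day as a block, 1887 within scan day 1, 2093 without single positive P4 replicate 1 and 0 with the files as attached (156 unadjusted). The oligodendrocyte precursor and astrocyte lists had median log2 differences of -2.16 and 3.29 as reported. These were -2.38 and 3.20 with slide as a block, -2.40 and 3.28 with scan day as a block, and -2.39 and 3.57 within scan day 1. Without single positive E14.5 replicate 3 Nfia (0.97, adjusted p = 0.12) did not pass, nor did Nfia (1.16, adjusted p = 0.0918) without P4 replicate 1, Nfia (1.36, adjusted p = 0.0619) with quantile normalisation and Nfia (0.97, adjusted p = 0.0653) with the mean of probes. The same held for Sox9 (1.98, adjusted p = 0.101) within scan day 1, Sox9 (1.67, adjusted p = 0.0551) with no filter on dim probes and Sox9 with any of 7 arrays left out in turn (1.37 to 1.81).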

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

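The change from E14.5 to P4 differed between populations by a test of the difference itself. For double positive against double negative cells the interaction was called for 7355 genes, and for double positive against single positive cells for 3192. No explanation is offered for these counts here. The report gives the leading genes with the change in each population.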

How the results depend on the processing

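The files as attached, the scanner signal with matched files, the omission of the floor or of dim arrays, slide and scan day in the model of group means, E14.5 alone and the fits within a scan day were chosen after the data had been seen. Each of the 12 counts of called genes stayed within 1.5 times its reported value, apart from those given here. With the files as attached the counts were, in the order of the report, 0, 0, 0, 0, 1057, 2441, 0, 328, 0, 1241, 0 and 0. At E14.5 alone, with fewer arrays, 6402, 4308 and 1565 genes were called for the 3 comparisons of populations. Within scan day 2, with 2 residual degrees of freedom, double positive against double negative cells gave 4010 and single positive against double negative 494. An additive model of slide, population and stage gave 4469 for double positive against single positive cells. With only the arrays compared, the counts were 393 at E10.5, 1932 for single positive and 891 for double negative cells from E14.5 to P4, 1924 for the middle stages and 3930 for the interaction with double negative cells. The middle stages gave 1493 without the 3 dimmest arrays and 377 within scan day 1, where the interaction with single positive cells gave 1887. The cause of these shifts was not tested where the number of arrays did not change.

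With each array left out in turn, and a lone array assumed to vary like the other groups, the count at E10.5 ran from 657 (without double negative replicate 3) to 1555, with 766 without replicate 1. Without single positive P4 replicate 1 the counts were lowest for single positive cells from E14.5 to P4 (2461, highest 3869), for the middle stages (533, highest 952) and for the interaction with single positive cells (2093, highest 3268). The other 8 counts stayed within 1.5 times their value when an array was left out. Of 3558 such refits of the 284 named values, 3500 kept direction and side of the threshold, 35 lost the call, 12 gained one and 11 reversed. The lowest and highest values were -0.23 and 0.11 for Arhgef4 in double positive cells from E14.5 to P4, -0.44 and 0.6 for Nfib in the interaction with double negative cells, and -0.19 and 0.16 for Sox9 at E10.5, none of which was called.

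Camera called 192 lists in all, 19 with an estimated correlation and 164 with the files as attached. So preset calls hardly tell the groupings apart. Whether replicate numbers, shared between groups, pair samples stays open. Of 23 same-numbered pairs, 9 had deviations correlated over 0.1 and 5 under -0.1 (-0.169 to 0.453). With the replicate number as a block no count moved by over 1.5 times, the furthest being the middle stages at 576, and 189 lists were called. A planned fit within a slide with 2 arrays of each population at P4 was not run, as no slide holds them.

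Some named values reversed direction, from causes not tested. With normexp they were Fut4 -0.68 in double positive and Fut4 -0.64 in single positive against double negative cells. Normexp gave Arhgef4 0.14 in double positive and -0.14 in double negative cells from E14.5 to P4, and 0.29 in their interaction. In double positive cells from E14.5 to P4 the matched scanner signal gave Arhgef4 0.17 and the replicate block Arhgef4 0. The block gave Sox9 0.04 in double positive against double negative cells at E10.5. E14.5 alone gave Fut4 -0.41 and Nusap1 0.37, and P7 as a further stage Fut4 -0.12, in double positive against double negative cells. E14.5 alone gave Nfib -0.18 in double positive against single positive cells. Single positive against double negative cells gave Fut4 -0.03, Fut9 -1.05, Pdgfrb 0.14 and Tmem119 0.22 at E14.5 alone. They gave Nfia -1.07, Nfib -0.01 and Slc1a3 -0.27 within scan day 1, and Fut9 -1.38, Pdgfrb 0.12 and Tmem119 1.41 within scan day 2. The value of Nfib in the interaction with double negative cells was -0.04 with the mean of probes, -0.21 with slide and -0.13 with scan day as a block, and -0.44 without the dimmest arrays. With the files as attached, 9 of the 284 named values kept direction and call, 99 lost the call and 176 reversed, as log2 changes. Double positive against double negative cells gave Arhgef4 -0.70, Cd68 -0.14, Dbx2 -0.72, F13a1 -0.63, Fut4 -0.50, Hes5 -0.82, Hey1 -0.37, Kcnj10 -0.40, Lyve1 -0.60, Ms4a7 -0.99, Nfia -1.31, Nfib -1.03, Olig1 -0.33, Pf4 -0.89, Rlbp1 -0.91, Slc1a3 -1.02, Sox2 -0.48, Sox9 -1.04, Syt1 0.62 and Ttyh1 -0.72. Single positive against double negative cells gave Alas2 2.19, Arhgef4 -0.62, Bcan -1.08, Bcas1 -1.44, Cldn5 1.28, Cnp -0.38, Egfl7 0.89, Fut4 -0.17, Fut9 -0.66, Gpr17 -0.74, Hba-ps4 2.40, Isg15 0.79, Lhfpl3 -0.64, Nfia -0.71, Nfib -0.85, Olig1 -0.89, Omg -1.09, Pdgfrb 0.29, Pnlip -0.42, Rlbp1 -1.66, Rsad2 1.09, Scrg1 -0.08, Slc1a3 -0.29, Slc4a1 1.62, Slc6a20a 1.74, Sox9 -0.36, Tmem119 0.73, Unc93a2 1.77 and Zdhhc22 1.53. Double positive against single positive cells gave Arhgef4 -0.08, Atf3 -0.82, Bcas1 2.07, Cspg4 0.28, F13a1 -0.09, Glul -0.56, Lhfpl3 1.41, Mapt 0.98, Mbp 1.39, Nfia -0.60, Nfib -0.18, Nfkbia -0.49, Oprl1 1.67, Pdgfra 0.25, Pf4 -0.15, Pnlip 1.06, S100b 0.44, Slc1a3 -0.73, Sox9 -0.68, Sstr1 1.57, Stab1 -0.25, Syt1 0.54 and Tmem130 0.56. Double positive against double negative cells at E10.5 gave Aif1 -0.45, C1qc -0.81, Ccl3 -0.47, Col3a1 1.89, Cx3cr1 -1.44, Ddr2 2.29, Fut9 -0.96, Gsx2 -0.83, Lum 1.59, Meox2 2.08, Mrc1 -0.77, Nfia 0.32, Nfib 0.60, Slc1a3 1.37, Sox9 1.59, Twist1 1.22 and Tyrobp -1.03. Double positive cells from E14.5 to P4 gave Arhgef4 3.07, Nfia 5.83 and Nfib 2.76. Single positive cells from E14.5 to P4 gave Arhgef4 3.81, Mfap4 0.67, Nfia 5.78, Nfib 3.76 and Sox9 0.23. Double negative cells from E14.5 to P4 gave Gda -1.48, Hoxb8 1.43, Ly6c1 -0.34, Mobp -0.39, Msln -1.33, Nfib 2.53 and Robo3 0.02. Double positive cells from E10.5 to E14.5 gave Aldh1l1 -5.67, Aldoc -5.61, Arhgef4 -3.09, Bcan -7.58, Cdt1 1.79, Cspg4 -5.56, Fndc3c1 4.75, Gapdh 0.78, Hbb-bh1 4.32, Hopx -6.01, Krt18 4.13, Krt8 5.31, Mmd2 -6.80, Mpo 5.60, Nfia -5.02, Nfib -3.64, Nfix -6.57, Oc90 4.28, Rlbp1 -5.79, Rrm1 1.66 and Sox9 -1.0. Double negative cells from E10.5 to E14.5 gave Actc1 4.50, Arhgef4 -1.79, Celf4 -1.04, Dusp9 3.64, Fndc3c1 5.79, Grm5 -8.04, Hbb-b2 -6.17, Hbb-bs -7.36, Hbb-bt -5.72, Kif20a 3.69, Meox1 2.32, Nfia -1.54, Nfib -1.77, Npy -3.22, Pax1 5.24, Sox2 2.10, Sox9 2.26 and Top2a 3.74. The middle stages gave Chst8 0.36, Clvs1 0.87, Fdps 0.14, Islr2 0.29, Ldha -0.64, Mobp 3.00, Nfia 1.86, Nfib 1.48, Pdlim2 0.85, Scn10a 1.91 and Sox9 -0.19. The interaction with double negative cells gave Car10 -0.63, Dclk3 -0.28, Grm5 -1.14, Mfsd2a 1.06, Nfia 2.81, Npy -1.57, Rsad2 0.23 and Sox9 0.80. The interaction with single positive cells gave Aqp4 -0.52, Arhgef4 -0.75, Bcas1 1.73, Dll3 4.25, Gsx1 3.04, Hey2 -0.67, Htra1 -4.35, Inava 4.66, Neu4 2.21, Nfib -0.99, Npy -5.30, Paqr6 -0.10, Sema5b 1.11 and Svep1 -2.12.

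Dim signal limits what can be compared. Genes not well above background in a group have bounds, and 7.29% of the gene values lay at the floor, where they have no order.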

Other observations

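For the 3 patterns weighed here, the tests on the single positive arrays, on the brightest genes, without E10.5, on the endothelial markers and on the variance between groups were chosen after the result was seen. Microglia and macrophage genes were higher in double positive cells than in both other populations. Low signal on the double negative arrays is argued against as the whole cause, since 29 of 31 members were also higher than in single positive cells, whose arrays were not dim. Macrophages or microglia among the sorted cells remain open. Whether the gate on dsRed removed cells without the reporter was not tested. The members, none of which is in another list, deviated together from group means over the 13 double positive arrays, with a mean pairwise correlation of 0.79, against at most 0.12 in 1000 random lists of matched level, 0.27 among astrocyte genes and 0.044 between both lists. The list mean spread most at E10.5 (0.32 ± 1.93), a stage outside the pattern: on the 10 other arrays the correlation was 0.51, against 0.42 among astrocyte genes. Uneven numbers of such cells may account for this, and their share was not measured.

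More genes changed from E14.5 to P4 in double negative than in double positive cells, 10266 against 5509. The order turned when each comparison was fitted on its own arrays, 891 against 5726, for 4 and 6 arrays, for a cause not tested. Values near background on the dim double negative arrays are argued against as the whole cause, but noise there stays open, as variances were pooled. Among the 4335 genes with the highest mean, 4317 of them well above background on every array, 67.6% were called in double negative and 45.5% in double positive cells. With each of the 10 arrays left out in turn these shares were at least 56.2% and at most 52.0%. Without the 3 dimmest arrays they were 57.3% and 53.3%, so part of the excess may come from those arrays. A changing mix of cells in the double negative gate may contribute, as 32 of 32 endothelial markers were higher at P4. Development within one cell type stays open and was not tested.

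For 40 columns of the value table the scanner file matched by ranks is attached to another sample. Scrambled columns are argued against, as groups explain 89.8% of the table's variance. Wrongly attached scanner files are a candidate, since groups explain 48.8% with the files as attached, within the highest of 100 label shuffles, 55.1%. Some levels run as the group names lead one to expect: Slc1a3 was highest in double positive cells at each stage from E14.5 to P4, and Hbb-y fell from E14.5 to P4 in double negative (16.88 to 9.65), single positive (15.63 to 4.06) and double positive cells (10.83 to 4.00). Yet Slc1a3 was below double negative cells in double positive ones at E10.5 (7.45 against 8.34) and single positive ones at P4 (10.6 against 11.24). An exchange of other names, such as neighbouring stages, stays open, and no biological explanation was tested.

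Other splits of the same arrays were drawn within stages, or within populations for the middle stages. These can part replicates, so they cannot tell the contrast from agreement of replicates. Of 100 splits only the real one reached its count for double positive against double negative cells (11494, highest other 10293). The same held for single positive against double negative (11658, 9569) and double positive against single positive cells (8429, 4710). For the middle stages 4 of 100 splits gave as many genes as the real 801, and the highest other gave 1491. For double positive cells from E14.5 to P4 (1 of 10, 5509, highest other 1) and from E10.5 to E14.5 (1 of 10, 8858, highest other 229) the splits are too few for a share under 0.05.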
